A study of Apostichopus japonicus with 9 samples.

How the data were processed

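Poly(A) RNA of the respiratory tree of the sea cucumber Apostichopus japonicus was sequenced on the BGISEQ-500 from 9 libraries, each made from RNA of 3 individuals pooled in equal amounts, per the labels' protocols. Animals had been kept for 3 days at dissolved oxygen of about 8 mg/L (DO8, the control), 4 mg/L (DO4) or 2 mg/L (DO2), with 3 libraries per group. The groups and replicate numbers were taken from the sample titles. The labels do not give tanks, so p-values measure the spread between pools within a group.

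Each deposited table lists, per the file headers, a gene model identifier, a length, an expected count and an FPKM value. The expected counts are the authors' estimated counts per gene model, not normalized. Between 50.5% and 56.0% of the models listed in a library had a whole-number estimate, meaning no decimal part in the deposited value. The remainder hold reads divided among models. The FPKM values were computed by the authors. A straight line was fitted in each library to abundant models of moderate length. It gave FPKM as the expected count divided by the length minus 36.5 and by a read total. That total was 3.3% to 4.9% above the sum of the listed counts. The relation was not checked for other models. CASAVA version 1.5 is named in the submitters' processing notes. The aligner, the counting program, the genome build and the annotation are not given in the sources used here.

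The 9 tables listed 27214 gene models in at least 1 library and 13133 in all 9. A model that a table did not list was taken as 0 in that library. Identifiers name a scaffold and a number, and the tables do not pair them with gene names; 0 of the 27214 identifiers matched the supplied table of 30661 RefSeq genes of this species (assembly ASM3797524v1). For this reason the 26 gene lists fixed before the data were examined (glycolysis, the HIF pathway, heat shock proteins, markers of muscle, gut, germ line and others) had no members to test, the camera tests were not run, and models are named by identifier. No coordinates are given. Of all models, 93.5% had a length divisible by 3, so the lengths are mostly coding lengths; 9 models longer than 100000 bases, all on scaffold 420, had lengths of up to 1761004 bases.

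Total expected counts ran from 1536327 (DO4 library 1) to 4348873 (DO2 library 3). A count of 0 allowed a level of up to 0.701 (DO4 library 3) to 2.55 (DO4 library 1) CPM, counts scaled to a fixed TMM-scaled total (3 counts per library). Such floors cover counting error only. Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest), with TMM factors, the default filterByExpr filter (13933 models kept, holding 98.9% of the counts) and 1 coefficient per group fitted to all 9 libraries. Benjamini-Hochberg adjustment was applied over the models tested, with a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic. Levels are CPM of the TMM-scaled library. Correlations used log2 CPM with a prior count of 2.

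The biological coefficient of variation across models was 61.1%. The test was tried on counts simulated from the means, library sizes and spread of these libraries with 200 changed models. It recovered 0.0% of 4-fold changes in each of the 3 comparisons. It recovered 62.4% of 16-fold changes for DO2 against DO8, 66.0% for DO4 against DO8 and 66.7% for DO2 against DO4, and 85.2%, 87.9% and 88.5% of 64-fold changes. On counts of 13933 models simulated in the same way, DESeq2 recovered more in the same order of comparisons, 20.5%, 17.5% and 25% of 4-fold changes and 85.5%, 79.5% and 81% of 16-fold changes. Its shares are of all 200 changed models, and those of edgeR are of the changed models its filter kept. It also called more unchanged models, 32, 35 and 40 beside the 4-fold changes and 59, 55 and 64 beside the 16-fold changes, against 0, 0 and 0 and 9, 6 and 5 by edgeR. With no changed model edgeR called 0 models in each comparison, and DESeq2 called 15, 20 and 7. The DESeq2 fits of the real counts held 27060 models, since no filter on low counts was applied first.

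Alternatives fixed with the gene lists were DESeq2 size factors and upper-quartile factors in edgeR, no filter on low counts, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) with and without a filter (FPKM of at least 1 in 3 libraries) and on log2(FPKM + 0.1) with it, fits of only the groups compared, voom with sample quality weights, the replicate number as a block, a minimum change of 2-fold, and leaving out each library. Leaving out DO2 library 3 together with DO4 library 1, thinning every library to 1536295 counts, and dropping the 28 models that are among the 10 most abundant of any library were added after the data were seen, as was the division of the DO8 libraries between the DO2 and DO4 comparisons. The rule for naming models, also set beforehand, took the largest changes past the threshold with no overlap between groups, at most 2 higher and 2 lower where identifiers have no names. No model passed the threshold, so the models named are the 2 higher and the 2 lower with the smallest p in each comparison among those with no overlap between groups and a mean log2 CPM of at least 1; that choice was made after their values were seen.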

Results

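The respiratory tree is the branched internal organ through which sea cucumbers exchange gas with sea water. Its transcripts were counted in 9 libraries from animals held at high, intermediate or low dissolved oxygen (DO8, DO4 and DO2), 3 libraries per group, each a pool of 3 animals. The DO8 libraries held 3478593, 3061618 and 2524054 expected counts. The DO4 libraries held 1536327, 2515330 and 3427221, and the DO2 libraries 2902222, 2429293 and 4348873. Between 17420 (DO4 library 1) and 21198 (DO4 library 3) gene models were listed per library. The files do not pair the model identifiers with gene names, so gene groups such as glycolysis or heat shock proteins could not be described.

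The libraries differed in what their counts were made of. In DO2 library 3 the 10 most abundant models took 52.7% of the counts, against 12.9% to 19.1% in the other 8 libraries. The consecutively numbered models evm.model.scaffold688.8 to evm.model.scaffold688.10 took 37.58% of the counts of that library, against 0.24% (DO2 library 2) to 4.17% (DO8 library 1) elsewhere. The neighbouring pair evm.model.scaffold661.14 and evm.model.scaffold661.15 took 4.26% there and 0.02% to 0.5% elsewhere. The TMM factor of DO2 library 3 was 0.458, and those of the other 8 libraries ran from 0.771 to 1.271. The deposited FPKM values carry no such correction: the median log2(FPKM + 1) of the tested models lay 1.2 lower in DO2 library 3, and 0.63 lower in DO4 library 1, than the median DO8 library.

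**Figure D1:**
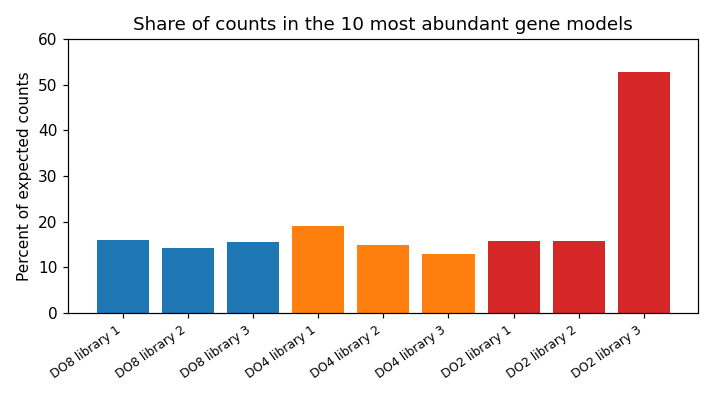
Share of each library's expected counts (percent, bars) taken by its 10 most abundant gene models, for the 3 libraries of each oxygen level. DO2 library 3 stands at 52.7%, and the other 8 libraries lie between 12.9% and 19.1%.

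Libraries of the control group were more alike than libraries of either low-oxygen group. Pearson's r of log2 CPM across models was 0.833 on average between DO8 libraries (range of the 3 pairs 0.830 to 0.835), 0.768 between DO2 libraries (0.756 to 0.781) and 0.742 between DO4 libraries (0.706 to 0.771). The median SD per model of log2 CPM was 0.46 in DO8, 0.63 in DO2 and 0.72 in DO4 (n = 3 each). No pair of libraries was alike enough to be one library deposited again.

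**Figure D2:**
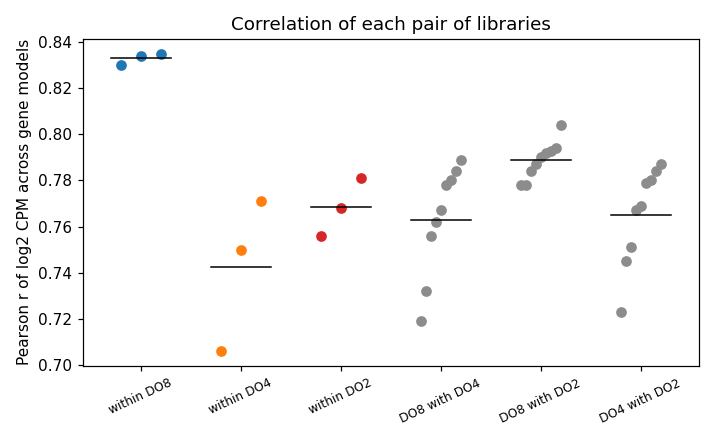
Pearson's r of log2 CPM across 13933 gene models (vertical axis, from 0.70) for each pair of libraries within or between oxygen levels; each point is a pair and the line is the mean. The 3 pairs within DO8 lie between 0.830 and 0.835, above every other pair.

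The comparison of DO2 with DO8 asks which transcripts differ after 3 days at about 2 mg/L, the level the submitters define as hypoxia. Model evm.model.scaffold1622.1 had 87.6 ± 70.8 CPM in DO2 (SD, n = 3) and no count in any DO8 library, which makes it at least 299-fold higher in DO2 (against 3 counts over the DO8 group, 0.293 CPM). The bound was 173-fold without DO2 library 3, 192-fold without DO8 library 1 and 191-fold without DO8 library 2. The DO4 libraries had 0, 0 and 0.47 CPM. Model evm.model.scaffold2424.5 had 42.1 ± 13.2 CPM in DO2 and 2.3 ± 1.66 in DO8, an 18.3-fold ratio of means (31.2-fold without DO8 library 3), and was at 7.66, 14.3 and 7.71 CPM in the DO4 libraries. Model evm.model.scaffold125.4 was 11.3-fold lower (19-fold without DO2 library 2), with 21.4 ± 15.3 CPM in DO2 and 242 ± 46 in DO8. The DO4 libraries, at 68.08, 42.58 and 31.54 CPM, were also below every DO8 library. Model evm.model.scaffold1621.6 was 3.79-fold lower, with 29.3 ± 4.91 CPM in DO2 and 111 ± 10.8 in DO8, and was at 17.02, 30.82 and 24.76 CPM in the DO4 libraries. Every DO2 library lay on the same side of every DO8 library for these 4 models, but none passed the threshold: edgeR's adjusted p was 0.322 for evm.model.scaffold1622.1, evm.model.scaffold2424.5 and evm.model.scaffold125.4 and 0.387 for evm.model.scaffold1621.6.

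Across the 13933 models tested, edgeR called 0 models between DO2 and DO8 after adjustment. At an unadjusted p under 0.05 there were 831 models, 380 higher and 451 lower in DO2; upper-quartile factors turned this balance, with 434 higher and 403 lower. The DO2 and DO8 libraries did not overlap in CPM for 14.2% of the models, where chance gives 10%. DESeq2 called 64 models, 27 higher and 37 lower, all 4 named models among them, and limma on log2(FPKM + 1) called 1, evm.model.scaffold1622.1. On uncorrected FPKM the median log2 difference of all models was -0.365, and 144 models were higher and 1151 lower at an unadjusted p under 0.05, a split that carries this shift. Leaving out each library in turn gave 0 calls and 638 to 1100 models at an unadjusted p under 0.05, with 1020 without DO2 library 3.

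The comparison of DO4 with DO8 asks the same of about 4 mg/L. The smallest p belonged to 2 models that were abundant in DO8 and scarce in DO4. Model evm.model.scaffold317.7 had 11.1 ± 4.37 CPM in DO4 and 431 ± 73.3 in DO8 (SD, n = 3), a 38.8-fold lower mean, with a log2 fold change of -5.28 ± 0.71 (SE) and an edgeR adjusted p of 0.185. Model evm.model.scaffold209.3 had 7.11 ± 1.93 CPM in DO4 and 253 ± 48.6 in DO8, a 35.6-fold lower mean, with a log2 fold change of -5.12 ± 0.61 and an edgeR adjusted p of 0.133, the lowest in any of the 3 pairwise comparisons. The DO2 libraries lay between these groups, at 60.84, 25.36 and 154.81 CPM for evm.model.scaffold317.7 and at 42.65, 55.87 and 166.95 CPM for evm.model.scaffold209.3. Both models passed the threshold in edgeR without the filter on low counts (adjusted p = 0.0126 and 0.0109), in edgeR fitted to DO4 and DO8 alone (0.0383 and 0.035), in edgeR without DO2 library 3 (0.0368 and 0.00944), in DESeq2 (1.04e-11 and 5.12e-13) and in limma on log2(FPKM + 1) (0.00258 and 0.00233), while over all alternatives their adjusted p reached 0.516.

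The consecutively numbered models evm.model.scaffold1207.5 and evm.model.scaffold1207.6 were higher in every DO4 library than in any DO8 library. The first had 66.6 ± 8.87 CPM in DO4 and 19.6 ± 2.23 in DO8, a 3.4-fold ratio, and the second 25.3 ± 4.28 and 5.76 ± 1.2, a 4.39-fold ratio; edgeR's adjusted p was 0.384 for both. The DO2 libraries held 94.08, 82.42 and 53.63 CPM of the first and 21.32, 17.43 and 12.14 CPM of the second. Across all models edgeR called 0 between DO4 and DO8 after adjustment and found 1188 at an unadjusted p under 0.05, of which 531 were higher and 657 lower in DO4; with upper-quartile factors, which moved the median log2 difference of all models from 0.054 to 0.135, 562 of 1250 were lower and the others higher. On uncorrected FPKM (median log2 difference -0.059) limma gave 331 higher and 808 lower. The DO4 and DO8 libraries did not overlap for 15.8% of the models, where chance gives 10% on average over splits. The share was not computed for other splits here either. DESeq2 called 125 models, 32 higher and 93 lower, and limma on log2(FPKM + 1) called 3, all lower.

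**Figure D3:**
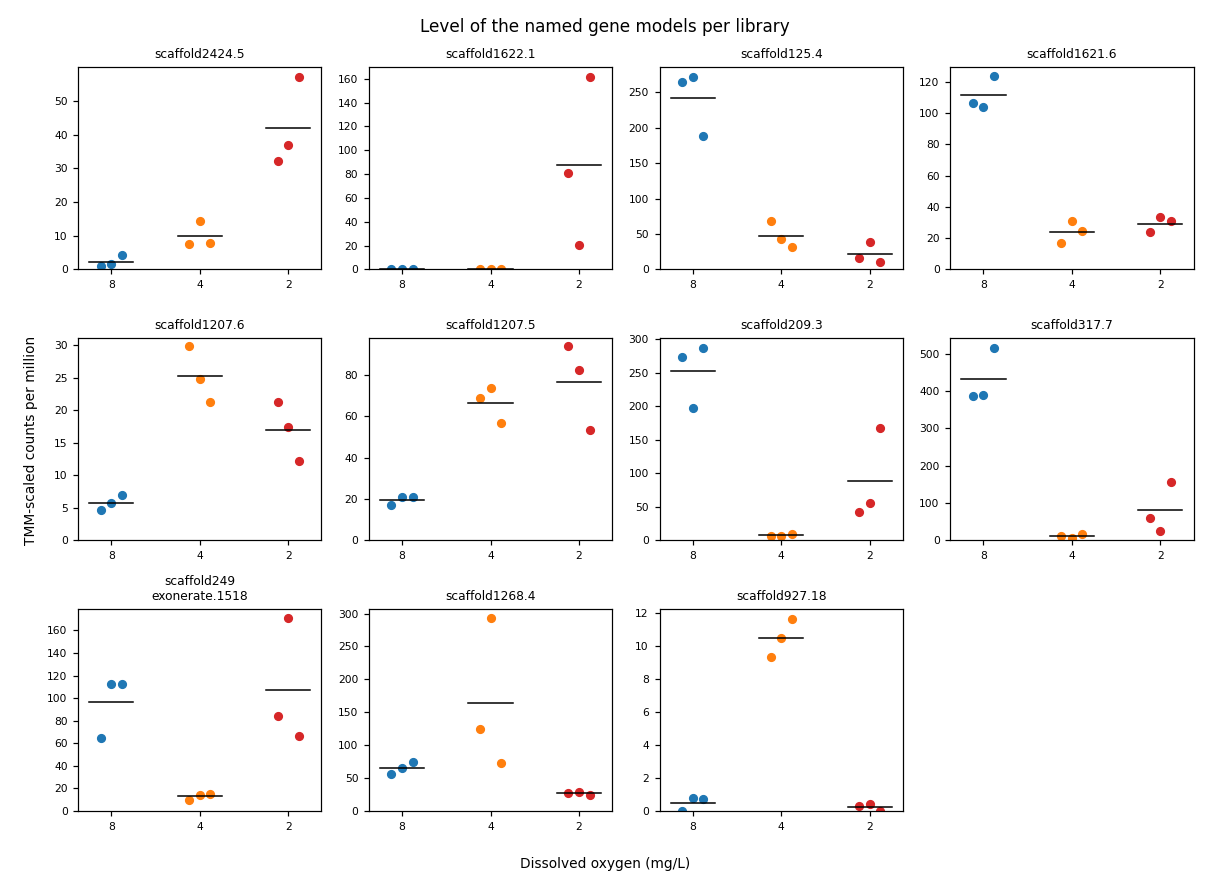
Level of the 11 named gene models in each library (vertical axis, TMM-scaled CPM, linear from 0 and scaled per panel) against dissolved oxygen (horizontal axis, mg/L); points are libraries and lines are group means. evm.model.scaffold209.3 and evm.model.scaffold317.7 are lowest at 4 mg/L, while evm.model.scaffold1622.1 is above 1 CPM in the DO2 libraries only.

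The comparison of DO2 with DO4 asks whether the lower oxygen levels differ from each other, which is also the test of whether their differences from DO8 are unequal. Model mRNA.scaffold249.extract.exonerate.1518 had 107 ± 55.9 CPM in DO2 and 13.1 ± 3.29 in DO4 (SD, n = 3), and its DO8 libraries, at 64.92, 112.47 and 112.23 CPM, resembled DO2 in level. Model evm.model.scaffold209.3 was also higher in DO2, at 88.5 ± 68.3 against 7.11 ± 1.93 CPM, a 12.4-fold ratio that was 6.93-fold without DO2 library 3. Model evm.model.scaffold1268.4 was 6.08-fold lower in DO2 (3.67-fold without DO4 library 2), at 26.9 ± 2.28 against 164 ± 115 CPM. Model evm.model.scaffold927.18 had 2 counts in all DO2 libraries together and 94 in DO4, a 42.0-fold ratio of pooled levels with an exact 95% counting interval of 11.3 to 352; it was at 0, 0.81 and 0.7 CPM in the DO8 libraries. EdgeR's adjusted p was 0.632 for the models that were higher and 0.971 for those that were lower.

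Across all models edgeR called 0 between DO2 and DO4 after adjustment and found 684 at an unadjusted p under 0.05, 410 higher and 274 lower in DO2. On uncorrected FPKM limma gave the opposite balance, 185 higher and 583 lower, with a median log2 difference of all models of -0.31. DESeq2 called 27, of which 17 were higher and 10 lower, and limma on log2(FPKM + 1) called 1. The libraries of these groups did not overlap for 7.7% of the models, below the 10% that chance gives on average over splits. That difference was not tested against other splits. EdgeR's test for any difference among the 3 groups called 0 models, with 944 at an unadjusted p under 0.05; DESeq2's likelihood-ratio test called 123 and limma on log2(FPKM + 1) called 4.

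**Figure D4:**
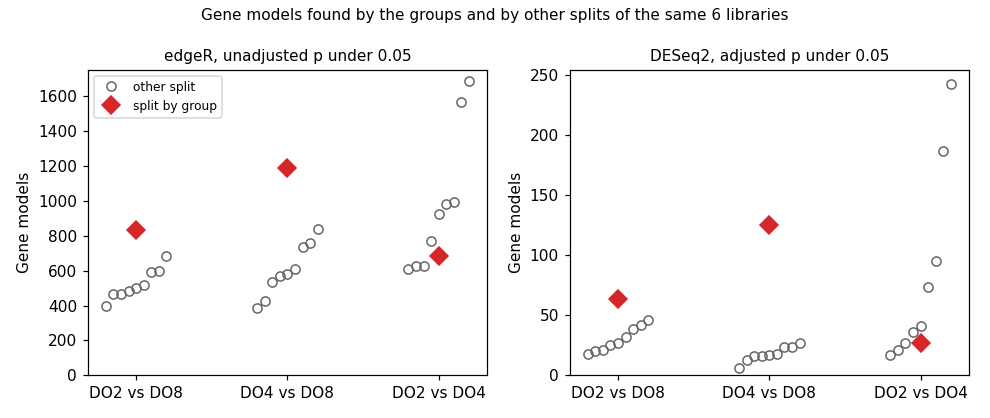
Number of gene models (vertical axis) found for the split of 6 libraries by group (diamonds) and for the other 9 splits of the same libraries (circles), by edgeR at an unadjusted p under 0.05 (left) and by DESeq2 at an adjusted p under 0.05 (right). The diamond is above every circle for DO2 against DO8 (831 and 64 models) and DO4 against DO8 (1188 and 125), and below most circles for DO2 against DO4 (684 and 27).

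The differences of DO2 and DO4 from DO8 were compared with each other across models, which are not independent replicates. Their log2 fold changes had a Pearson's r of 0.547, and 70.5% had the same sign. Both comparisons use the same DO8 libraries, and 20 simulated sets with no effect gave an r of 0.488 and 66.3%. Those sets gave all groups the same spread per model. The real DO8 libraries spread less (median SD 0.46, against 0.63 in DO2 and 0.72 in DO4). The simulated values may therefore lie above what the shared controls alone give. Each model was also drawn independently, whereas consecutively numbered real models differed together, and only means over the 20 sets are given. No other split of the real libraries was run for these values. A difference from the simulated values is therefore not a measure of a shared response. The covariance was 0.569 against 0.335 in the simulated sets, a difference of 0.234. At an unadjusted p under 0.05, 149 models were higher in both and 179 lower in both, while 2 went opposite ways; the simulated sets gave 94.8 and 39.5, and independent lists would share 14.5 and 21.3. The balance depended on the scaling, with 199 higher and 142 lower under upper-quartile factors and 37 higher and 368 lower by limma on log2(FPKM + 1). By DESeq2 7 models were called higher in both, 13 lower in both and 0 opposite, where independent lists would share 0 and 0.1. These calls also share the DO8 libraries, and no shared-control value was simulated for them, so the excess over independent lists is not a measure of a shared response. On log2 CPM the covariance of the differences was 0.414, and the variance of the DO8 mean, which both differences contain, was 0.228. With the DO8 libraries divided 1 against 2, so that DO2 and DO4 were compared with separate controls, the covariance over the 6 divisions was 0.173 to 0.201 and r was 0.173 to 0.206. Positive values also follow from DO8 libraries being more alike than libraries of different groups. They cannot be told apart from differences between tanks or batches, which the labels do not give. The divisions reuse the same libraries, so their range is not an uncertainty. No other set of 3 libraries was tried as the control.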

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

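Among the tests on the abundant models of DO2 library 3, that of their summed share was chosen after its result was seen.

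Groups of 3 libraries are too small for a test of a single distant value, so measures of whole libraries were examined over all 9 with Dixon's 95% critical value. Chance passes it in about 0.05 of cases for a single measure. Several measures were examined, so a passing value somewhere among them is likelier than that. DO4 library 1 listed 17420 models, fewer than any other (the next lowest, DO8 library 3, listed 19786), and had the lowest total count. The read total estimated from the FPKM values of DO2 library 3 was 3.3% above its listed counts, against 4.3% to 4.9% in the other libraries.

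DO2 library 3 was set apart by the 52.7% of its counts in 10 models and by the 37.58% in 3 consecutively numbered models, evm.model.scaffold688.8 to evm.model.scaffold688.10. The 3 models were picked from the 10 most abundant of this library, so their share is not a separate finding. Of their 27 expected counts 0.0% were whole numbers (no decimal part), as reads shared between neighbouring copies require, so the level of each model alone is uncertain. Reads shared with any other model would give the same, most readily in abundant models. The share for equally abundant models was not computed, so the result does not single out neighbouring copies. Their sum, 37.58% against at most 4.17% elsewhere, is the value that set the library apart and so tests nothing further about reads shared among the 3. The log2 ratios between the 3 models had SDs over the 9 libraries of up to 0.52 while each model ranged over 7.88 to 9.21 log2 units, which leaves open whether one source of RNA brings them in a fixed ratio; without names for the models no biological explanation was tested. Whether these models hide changes in DO2 vs DO8 is also open: leaving the library out gave 0 calls, no more than leaving out either other DO2 library, but the count was at its lowest possible value in all 3 cases and so decides nothing.

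For 18 models every DO2 library lay on one side of all DO8 libraries and every DO4 library on the other (12 with DO2 above and 6 with DO2 below), where random order of the libraries would give 16.6; the difference was not tested per model beyond the DO2 against DO4 comparison.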

How the results depend on the processing

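In simulated counts with the spread of these libraries (13223 to 13347 models tested) edgeR recovered no 4-fold change, so changes of that size were not detectable by this test here; DESeq2 recovered 17.5% to 25% of them. The 0 calls of each comparison and of the 3-group test stayed at 0 with DESeq2 size factors, upper-quartile factors, voom quality weights, thinned counts, dominant models left out, and DO2 library 3 and DO4 library 1 left out together (the last 3 settings were chosen after seeing the data). A minimum change of 2-fold cannot raise a count of 0 and says nothing about stability. DESeq2 called 64 models for DO2 against DO8, 125 for DO4 against DO8, 27 for DO2 against DO4 and 123 among the 3 groups; these fits held 27060 models, and in simulated data of 13933 models with no effect it called 15, 20 and 7 for the pairs. Without the filter on low counts edgeR called 2 for DO4 against DO8 and 4 among the groups, and with only DO4 and DO8 fitted 2. Limma on log2(FPKM + 1) called 1, 3, 1 and 4 in that order of comparisons, on log2(FPKM + 0.1) 1, 3, 0 and 3, and without its filter 1, 3, 0 and 3. Equal counts were not always the same models. For DO2 against DO8 evm.model.scaffold1622.1 was called on log2(FPKM + 1), but had a limma adjusted p of 0.0746 on log2(FPKM + 0.1). For DO4 against DO8 all 3 were lower on log2(FPKM + 1), while 1 was higher and 2 lower on log2(FPKM + 0.1). The cause of these differences was not tested. Leaving out each library gave 0 calls for DO2 against DO8, 0 to 2 for DO4 against DO8 (2 without DO2 library 3), 0 to 1 for DO2 against DO4 (1 without DO4 library 3 and 1 without DO8 library 3) and 0 to 1 among the groups (1 without DO2 library 3). The r between the DO2 and DO4 responses ranged from 0.45 to 0.643 over these fits and was 0.506 by DESeq2. The lowest lies below the 0.488 simulated for all 9 libraries with no effect. No such value was simulated for the alternative fits, so their r alone does not measure a shared response.

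Of the 264 values of the 12 named results under alternatives, 26 came past the threshold, 12 of them under DESeq2; that 0 changed direction follows largely from naming only models whose groups did not overlap. The replicate numbers did not pair the libraries: the correlation of deviations between libraries with the same number ran from -0.17 to 0.07, and 1 of 9 libraries correlated best with its own number. With the replicate block edgeR called 0 models in each comparison, and r was 0.569. The tests of gene lists and their alternatives were not run because no model could be assigned to a list.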

Other observations

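The tests of DO8 against the 6 low-oxygen libraries, of DESeq2 calls over other splits, of the rank of the DO8 libraries in pair correlation, of one aberrant library per group and of a wider spread at lower oxygen were chosen after their results had been seen.

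Some models separated DO8 from both lower oxygen levels. All 6 low-oxygen libraries lay above every DO8 library for 282 models and below for 406, where chance gives 2.38% of 13933, and 4 of the 84 splits of the 9 libraries into 3 and 6 separated as many in all, the real one included, with 882 as the highest. The smallest p belonged to evm.model.scaffold1621.6, which held 106.31, 104.09 and 123.77 CPM in DO8 and 17.02 to 33.28 CPM in the low-oxygen libraries, followed among the higher models by evm.model.scaffold1207.5 at 17.04 to 20.98 CPM in DO8 and 53.63 to 94.08 CPM elsewhere. In edgeR neither passed (adjusted p = 0.195 and 0.209), 0 models were called, 1167 had an unadjusted p under 0.05, and leaving out any library also gave 0 calls. In that count 6 of the 84 splits gave as many, with 1708 as the highest, so chance was not excluded for it. The count of separated models was the third statistic tried on this grouping, after 0 calls and 6 of 84 splits, and the smaller spread of the DO8 libraries (median SD 0.46 against 0.63 and 0.72) also bears on it, so its 4 of 84 is weak evidence. In 17 models the groups lay in the order DO8, DO4, DO2 from highest to lowest without overlap and in 13 in the reverse order. Random order of all 9 libraries would give 8.3 each. These models are part of the 406 and 282 in which DO8 already lay apart, which that value ignores. The counts therefore do not test an order between DO4 and DO2. Models with 10 or more counts in every library of one group and 0 in every library of the other were few: 3 in DO2 alone and 1 in DO8 alone, 1 in DO4 against 4 in DO8, and 2 in DO2 against 0 in DO4, with up to 4, 7 and 9 for other sets of 3 of the same libraries.

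For DO2 against DO8 the real split gave more models than any of the other 9 splits of the same 6 libraries: 831 against at most 682 at an unadjusted p under 0.05 in edgeR, and 64 against at most 46 DESeq2 calls, so the real split alone reached that count (1 of 10 splits) in both tools. For DO4 against DO8 it was again 1 of 10, with 1188 against at most 836 models in edgeR and 125 against at most 27 DESeq2 calls. A design of 10 splits cannot give a share under 0.05. For DO2 against DO4, 7 of 10 splits gave as many models in edgeR (684, highest other 1686) and 8 of 10 in DESeq2 (27, highest other 243). For the 3-group test 17 of 100 splits gave at least the real 944 models, with 1768 as the highest, so chance was not excluded. The split that put DO2 library 1 with DO4 libraries 2 and 3 gave 1686 models in edgeR and 187 DESeq2 calls, and the split that put DO2 libraries 1 and 2 with DO4 library 3 gave 1567 and 243. Both set DO2 library 1 and DO4 library 3 against DO2 library 3 and DO4 library 1, which points to a structure of the libraries that the labels do not name and that was not tested. DO2 library 3 and DO4 library 1 also had the lowest TMM factors, 0.458 and 0.771. On the other side, DO4 library 3 had the lowest voom quality weight, 0.54, followed by DO4 library 1 at 0.85. The r of 0.706 between DO4 libraries 1 and 3 was the lowest of any pair of libraries.

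The 3 DO8 libraries had the highest mean pair correlation of the 84 sets of 3 libraries (0.833, next 0.81; exact one-sided permutation p = 0.0119, the smallest these libraries can give), while DO2 had 0.768 and DO4 0.742. DO8 was not named before its rank was seen, and any of the 3 groups could have ranked first, so this p is too small. A difference in library depth was argued against by thinning, after which DO8 still ranked first and its lead over the mean of the other groups was 0.075, against 0.078 before. Thinning made total counts equal, but not the counts outside the dominant models, which stayed low in DO2 library 3. The best pair after thinning had an r of 0.791 in DO2 and 0.78 in DO4, below the lowest DO8 pair at 0.838. With the 28 dominant models left out DO8 also ranked first, with a lead of 0.08. That removed few of the 13933 models, which all weigh the same in r. It also did not restore the counts that other models lacked in DO2 library 3. The result therefore does not decide whether a few models taking most of the counts caused the lead. One aberrant library per group was argued against by the best pair within DO2 or DO4, whose r of 0.781 lay below the lowest DO8 pair at 0.830. That lower oxygen makes pools of animals differ more is a candidate explanation for the lead of 0.078, and it cannot be told apart from differences between tanks or batches, which the labels do not give.

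Consecutively numbered models on a scaffold differed together. Over 6253 such pairs the correlation of the log2 difference between groups was 0.19 to 0.207, against values near 0 after shuffling (-0.017 to 0.016). Reads shared between neighbouring models are argued against as the whole cause, since the 2315 pairs whose expected counts were whole numbers in every library still had a mean r of 0.162, with bootstrap SEs over scaffolds of up to 0.026. Dissolved oxygen as the only source is argued against too, since the same correlation between libraries of one group averaged 0.185, 0.016 less than between groups; in whole-number pairs it averaged 0.125 (0.072 to 0.182) against 0.162 (0.126 for DO2 against DO4, 0.172 for DO4 against DO8 and 0.187 for DO2 against DO8), so a smaller part stays open. Nearby genes that vary together between pools, or one gene divided into several models, may both account for it, and neither was tested.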
